A study of Homo sapiens with 6 samples.

How the data were processed

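Polyadenylated RNA was sequenced from cortical organoids at day 14 of culture, grown from the human embryonic stem cell line H9. The labels put the 6 libraries in 3 groups of 2: the unedited line (WT, CHD7 +/+) and CHD7 knockout clones made with CRISPR-Cas9, named KO1 and KO2. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The chi-square per degree of freedom between the 2 libraries of a group was 56.77 in WT, 12.83 in KO1 and 45.09 in KO2. This is more than repeated sequencing of the same RNA would give, but it does not tell separate cultures from separate library preparations. WT replicate 1 had lower values against KO1 replicate 1 (39.64), KO1 replicate 2 (43.26) and KO2 replicate 2 (40.84) than against WT replicate 2. Against KO2 replicate 1 its value was higher (69.62). KO2 replicate 2 had lower values against KO1 replicate 1 (23.2) and 2 (32.84) than against KO2 replicate 1. Only the KO1 libraries were nearest to each other.

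The authors deposited 2 tables of raw read counts per gene, each with the WT columns and the columns of 1 clone. Per the file headers, the counts were made with featureCounts 2.0.1 in paired-end mode, summing exons per gene of a RefSeq annotation of hg19, with no strand option. HISAT2, DESeq2 and hg19 are named by the submitters' processing notes. The columns with the prefix con were read as the WT libraries, because no other group is an unedited control, and these columns held the same counts in both tables. Counting without strand means that reads from a gene and an overlapping antisense gene cannot be told apart, and reads can be split among near-identical genes. The authors also deposited 1 table of changed genes per clone, with a log2 fold change and an adjusted p-value for each gene, from DESeq2 per the submitters' processing notes. The deposited table of KO1 held lower genes only and that of KO2 held higher genes only, so each was treated as a part of a comparison. Their gene positions differ from those of the hg19 count tables and their build is not given in the sources used here, so no position was taken from them.

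All 6 libraries were fitted together. The tables held 27979 genes, of which 5491 had no count in any library. After the edgeR function filterByExpr, 16285 genes were tested with edgeR 4.0.16 (R 4.3.3), using TMM factors, which lay between 0.978 and 1.012, and the quasi-likelihood test. The common biological coefficient of variation was 0.264, with 3 residual and 3.41 prior degrees of freedom. Contrasts were KO1 minus WT, KO2 minus WT, the mean of both clones minus WT, and KO2 minus KO1. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are given as CPM (counts scaled to the library size) with the SD over 2 libraries.

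The 30 gene lists were fixed before the data were examined, with 731 memberships of 677 genes, of which 574 genes were tested. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. camera asks whether a list moved relative to all other genes. fry, run as an alternative, asks whether the members moved on balance in 1 direction. Counts of single members are given over all genes tested and adjusted over the list alone.

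The rule for named genes was also fixed before the data were examined. It took CHD7, then genes past the threshold whose libraries all lay beyond both WT libraries and whose mean was at least 5 CPM in the higher group: the 8 largest rises and falls per clone, 12 per direction for genes called in both clones, and 6 per direction for KO2 against KO1. From each list it took up to 4 members of smallest adjusted p in the mean of both clones and up to 4 in either clone. The same selection of 12 per direction for the mean of both clones was added after the data were seen. XIST, Y-linked and mitochondrial genes were left out, and so were symbols of uncharacterised loci. Genes outside the rule that are named below, among them single stem cell genes, ZNF737 against WT and members of long lists, were chosen after their values were seen. Some genes that the rule selects are not reported here.

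A group with no count was given a floor of 3 counts over the group, and the fold is then a lower bound. With 1 to 3 counts the ratio of summed counts per total is given with an exact 95% counting interval. Such bounds and intervals cover counting error only. In 1 library a single count was worth between 0.0535 and 0.0716 CPM.

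Because both clones were compared with the same WT libraries, 50 data sets were simulated in which all 6 libraries were drawn from 1 mean per gene. The covariance with 1 WT library against each clone was added after the data were seen. The fits were tested on simulated data of 16037 genes with changed genes of known size. For KO1 minus WT, edgeR recovered 13% of the genes changed by a log2 fold change of 1, 77.8% at 2 and 83.6% at 3, and 12.1% of its calls were false. For the mean of both clones it recovered 30.4%, 87.3% and 96.7%, with 11.8% false calls. DESeq2 recovered 46.4%, 90.5% and 90.2% for KO1, with 29.1% false calls. False calls were therefore more frequent than the nominal 5% with both tools. A simulated rise of 1 list gave that list a camera adjusted p of 6.78e-25, and 1 other of the 30 lists also passed the threshold.

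Alternatives were RLE size factors, no low-count filter, a filter of 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, fits of only the 2 groups compared, each library left out in turn, and for lists an estimated correlation and fry. The alternatives for lists between the clones and for chromosomes were added after the data were seen. Leaving out a library left 1 in its group, which was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.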

Results

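Gene expression was measured by RNA sequencing in day 14 cortical organoids, which are free-floating aggregates of stem cells guided toward forebrain tissue. They came from the human embryonic stem cell line H9 and from 2 clones of it, KO1 and KO2, in which the gene for the chromatin remodeler CHD7 had been edited. Each group had 2 libraries. The counts assigned to genes per library lay between 13973950, in KO1 replicate 2, and 18700646, in KO2 replicate 1. The 2 WT libraries differed at least 2-fold in 2254 of the 16285 genes tested, the KO1 libraries in 812 and the KO2 libraries in 1575. The WT libraries also differed in cell type markers: the forebrain list had a mean log2 CPM of 3.33 in replicate 1 and 4.58 in replicate 2, and the list of postmitotic neurons 6.4 and 4.9.

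CHD7 (chromosome 8, 61591324 to 61780586, hg19) was reported first because it is the targeted gene. Its counts were 7382 and 7194 in the WT libraries, 2577 and 2343 in KO1, and 3429 and 3591 in KO2. The levels were 434.5 ± 9.59 CPM in WT, 162.3 ± 6.77 CPM in KO1 and 192.5 ± 15.5 CPM in KO2 (SD, n = 2 each), so every clone library lay below every WT library. The log2 fold change was -1.42 (SE 0.137) in KO1, with an edgeR quasi-likelihood adjusted p of 0.0272, and -1.30 (SE 0.112) for the mean of both clones, with an adjusted p of 0.011. In KO2 it was -1.18 (SE 0.136), which did not pass with edgeR (adjusted p = 0.0524) and passed with DESeq2 (adjusted p = 1.29e-10). The clones did not differ detectably from each other (log2 fold change 0.25, edgeR adjusted p = 0.788). The KO1 call was lost without WT replicate 2 (adjusted p = 0.0659), KO1 replicate 1 (0.347), KO1 replicate 2 (0.277), KO2 replicate 1 (0.0765) or KO2 replicate 2 (0.0783), and the fold change then stayed between -1.46 and -1.38. The call for the mean of both clones was lost without KO1 replicate 1 (0.144), KO1 replicate 2 (0.0945), KO2 replicate 1 (0.0718) or KO2 replicate 2 (0.0629). Counts summed over exons do not show whether the remaining transcripts carried the edit.

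The comparison of KO1 with WT asked which genes change in organoids when CHD7 is edited. Transcription factors of the forebrain fell and a hindbrain factor rose. OTX1, a homeobox factor of the forebrain and midbrain (chromosome 2, 63277192 to 63284966), fell from 196.2 ± 48.5 CPM to 0.433 ± 0.0937 CPM (SD, n = 2 each; log2 fold change -8.81, SE 0.323, edgeR adjusted p = 0.00114). PAX6, a factor of cortical progenitors and the eye (chromosome 11, 31806340 to 31839509), fell from 219.1 ± 27.9 to 6.46 ± 1.77 CPM (-5.08, SE 0.298, edgeR adjusted p = 0.00414). This PAX6 call was lost without KO1 replicate 1 or 2. HOXB2, a homeobox factor of the hindbrain (chromosome 17, 46620019 to 46622393), rose from 9.3 ± 4.39 to 150.7 ± 13 CPM (4.02, SE 0.342, edgeR adjusted p = 0.0194). The HOXB2 call was lost without KO1 replicate 1 (0.162), KO1 replicate 2 (0.0982), KO2 replicate 1 (0.0873) or KO2 replicate 2 (0.0866).

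Several other regulators moved in KO1. TCF7L2, a transcription factor of WNT signalling, fell by 2.00 on the log2 scale (edgeR adjusted p = 0.0156), and LGR5, a receptor for R-spondins and a WNT target, fell from 38.8 to 0.993 CPM (-5.28, adjusted p = 0.00863). EMX2OS, which overlaps the cortical factor EMX2, fell by 7.31, and the protocadherin PCDHB5 fell by 5.52 (adjusted p = 0.0383 and 0.041). OTX2-AS1, antisense to OTX2, had 311 counts in WT and 3 in KO1, a ratio of 93.2 (95% counting interval 31.6 to 454, adjusted p = 0.0468). CARTPT, which encodes a neuropeptide precursor (chromosome 5, 71014990 to 71016875), had 1 count in WT and 961 in KO1, a ratio of 1070 (95% counting interval 191 to 42300, adjusted p = 0.0154). RAB3C, a vesicle GTPase of neurons, rose from 17.2 to 68.5 CPM (1.99, adjusted p = 0.0249), while its KO2 value was 1.02, which did not pass, and the clones did not differ detectably (adjusted p = 0.29). ZNF703 rose by 1.79, the palmitoyltransferase gene ZDHHC4 by 2.39 and the thioesterase gene ACOT2 by 4.38 (adjusted p = 0.0295, 0.041 and 0.0235). The calls of EMX2OS, PCDHB5, OTX2-AS1, CARTPT, RAB3C, ZNF703 and ZDHHC4 were lost without KO1 replicate 1 or 2 (adjusted p between 0.0677 and 0.347) and without KO2 replicate 1 (0.0515 to 0.111). All of these except CARTPT were also lost without KO2 replicate 2 (0.0617 to 0.11), and all except CARTPT and EMX2OS without WT replicate 2 (0.06 to 0.0964).

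A further set of genes had 0 counts or low levels in KO1, and 1 gene was the reverse. CHCHD2, a mitochondrial protein gene (chromosome 7, 56169255 to 56174323), had 1439 and 1737 counts in WT and 0 in both KO1 libraries, at least 952-fold lower (edgeR adjusted p = 0.00136). The zinc finger genes ZNF229 and ZNF737 were also at 0 counts in KO1, at least 150-fold and at least 36.9-fold lower (adjusted p = 0.00919 and 0.025). In the other direction, ZNF141 had 0 counts in WT and 747 in KO1, at least 277-fold higher (adjusted p = 0.0187). TTN, the giant sarcomere protein gene (chromosome 2, 179390717 to 179672150), fell from 47.6 ± 0.0649 to 1.33 ± 0.238 CPM (-5.16, adjusted p = 0.00136), and PKIB, an inhibitor of protein kinase A, fell by 4.35 (adjusted p = 0.00414). The ZNF229 and ZNF141 calls were lost without any 1 of the 4 clone libraries (adjusted p between 0.0583 and 0.0774, and between 0.054 and 0.187). Reads of zinc finger genes and protocadherins can be shared with paralogs, and those of TTN with its antisense gene.

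With edgeR, 24 genes were called in KO1, 7 higher and 17 lower, all at least 2-fold, and 1812 genes had an unadjusted p under 0.05. DESeq2 called 530 genes, 278 higher and 252 lower, and these included all 24. The count was 212 without WT replicate 1, 26 without WT replicate 2, 2 and 3 without KO1 replicate 1 and 2, and 8 and 9 without KO2 replicate 1 and 2. In that order, 24, 15, 2, 3, 7 and 8 of the 24 genes were still called. All 24 kept their sign in each of these fits. OTX1 and CHCHD2 kept their calls in every fit that left out 1 library. Every other gene of the 24 lost its call without KO1 replicate 1, among them PAX6, TCF7L2, ACOT2, PKIB and ZNF737. TTN lost its call only there, with a log2 fold change of -4.99. LGR5 lost its call without KO1 replicate 1 or 2, at -5.18 and -5.39.

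The comparison with WT was repeated for KO2, the second clone. OTX1 fell to 0.382 ± 0.059 CPM (log2 fold change -8.97, SE 0.322, edgeR adjusted p = 0.001) and PAX6 to 35.7 ± 8.69 CPM (-2.62, SE 0.261, adjusted p = 0.0409). HOXB2 rose to 133 ± 16 CPM (3.84, SE 0.34, adjusted p = 0.0268) and CARTPT had 1088 counts against 1 in WT, a ratio of 995 (95% counting interval 178 to 39300, adjusted p = 0.0169). The WNT ligand genes WNT2B and WNT4 fell: WNT2B, a ligand of the dorsal midline, from 129.8 ± 41.3 to 7.77 ± 0.09 CPM (-4.06, SE 0.274, adjusted p = 0.00904), and WNT4 from 129.3 ± 10 to 16.4 ± 2.76 CPM (-2.98, SE 0.197, adjusted p = 0.00904). TPBG, a membrane glycoprotein gene, fell from 820.2 to 124.6 CPM (-2.72, adjusted p = 0.00882). The PAX6 call was lost without KO1 replicate 1 (0.081), KO1 replicate 2 (0.082), KO2 replicate 1 (0.213) or KO2 replicate 2 (0.0762), the WNT2B call without KO2 replicate 1 (0.182) or 2 (0.0618), and the WNT4, TPBG and CARTPT calls without KO2 replicate 1 (0.117 for each). The HOXB2 call was lost without KO1 replicate 1 (0.081), KO1 replicate 2 (0.0825), KO2 replicate 1 (0.211) or KO2 replicate 2 (0.0618).

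ZDHHC4 rose from 1.49 to 44.1 CPM in KO2 (4.88, edgeR adjusted p = 0.00558), ACOT2 by 5.50 (adjusted p = 0.0124) and ZNF703 by 2.13 (adjusted p = 0.0201). EMX2OS fell by 7.22 and PCDHB17P, a protocadherin pseudogene whose reads may come from paralogs, by 5.35 (adjusted p = 0.0448 and 0.0497). OTX2-AS1 had 0 counts in KO2, at least 113-fold lower (adjusted p = 0.0402). The calls of ZNF703, EMX2OS, OTX2-AS1 and PCDHB17P were lost without any 1 of the 4 clone libraries (adjusted p between 0.0618 and 0.353), that of PCDHB17P also without WT replicate 1 (0.0595), and that of ACOT2 without KO1 replicate 1 (0.0593), KO1 replicate 2 (0.0541) or KO2 replicate 1 (0.117). LGR5 and TCF7L2 had log2 fold changes of -2.73 and -1.27 that did not pass (adjusted p = 0.0524 and 0.0539). edgeR called 17 genes in KO2, 5 higher and 12 lower, and 1692 genes had an unadjusted p under 0.05. DESeq2 called 521, 281 higher and 240 lower, with all 17 among them. The edgeR count was 58 and 65 without WT replicate 1 and 2, 10 and 11 without KO1 replicate 1 and 2, 3 without KO2 replicate 1 and 25 without KO2 replicate 2, and every one of the 17 genes kept its sign. In that order, 16, 17, 7, 7, 2 and 7 of the 17 genes were still called. OTX1 and ZDHHC4 kept their calls in each of these fits.

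Genes called in both clones numbered 12, all in the same direction. The 5 higher genes were CARTPT, HOXB2, ZDHHC4, ZNF703 and ACOT2. The 7 lower genes were OTX1, PAX6, EMX2OS, OTX2-AS1, PCDHB17P and the uncharacterised loci LOC100132215 and LOC90768. The comparisons share their WT libraries, so unchanged groups were simulated against common controls: 50 simulations gave 0.02 such genes on average and at most 1. Independent lists of these lengths would share 0.0021 higher and 0.013 lower genes. Across all genes, which are not independent replicates, the covariance of the log2 fold changes was 0.448 against a simulated 0.108, a difference of 0.34, and the measured spread of the WT libraries would give 0.203, leaving 0.245. The correlation was 0.555 against 0.5, and 72.3% of genes had the same sign against 66.6%. The simulation gave every group the same spread for a gene, and its covariance of 0.108 lay below the 0.203 of the measured WT spread. Its average of 0.02 shared calls may therefore be too low a reference for the 12 observed. With 2 WT libraries no split leaves 2 per comparison, and part of the excess may come from the shared controls. With 1 WT library against each clone, so that none was shared, the covariance on log2 CPM was 0.353 and 0.235 in the 2 possible pairings, against 0.496 with both shared. The number of shared calls was 47 and 15 without WT replicate 1 and 2, 1 without either KO1 library, 2 without KO2 replicate 1 and 4 without KO2 replicate 2, and DESeq2 gave 240.

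The mean of both clones against WT asked which changes accompany the editing of CHD7 averaged over the clones. Besides OTX1 (log2 fold change -8.89, SE 0.236, edgeR adjusted p = 0.000146) and PAX6 (-3.85, SE 0.213, adjusted p = 0.00398), factors that pattern the dorsal forebrain and its midline fell. EMX2, a factor of the developing cortex, had 1222 counts in WT, 1 in KO1 and 4 in KO2 (adjusted p = 0.0121), although the WT libraries themselves held 258 and 964. DMRT3 had 335 counts in WT and 0 in both clones, at least 100-fold lower in KO1 and at least 122-fold lower in KO2 (adjusted p = 0.0434), a call that DESeq2 did not make (adjusted p = 0.227). The midline ligand genes WNT8B and RSPO2 fell by 3.49 and 6.88 (adjusted p = 0.0298 and 0.0125). The homeobox genes DMBX1, BARHL2 and DBX1 fell by 5.16, 3.64 and 4.83 (adjusted p = 0.0277, 0.0298 and 0.0306), and POMC, a hormone precursor gene, by 3.82 (adjusted p = 0.0482).

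Further genes rose in the mean of both clones, among them transcripts of HOX clusters. HOTAIRM1, a transcript of the HOXA cluster, rose by 3.94 and HOXB-AS1, which overlaps HOXB2 and HOXB3, by 2.68 (edgeR adjusted p = 0.0406 and 0.0298). TBX10 rose by 3.40, the glutamate receptor gene GRIK3 by 2.57, the protease gene PRSS12 by 2.37, the transporter gene SLC15A3 by 2.25, the receptor tyrosine kinase gene RET by 2.21 and AJAP1 by 2.16 (adjusted p between 0.0298 and 0.0434). Guidance and adhesion genes moved both ways: SLIT1 rose by 1.20 (adjusted p = 0.0403), whereas EPHA7 fell by 1.83 and CDH2, the N-cadherin gene of neuroepithelium, fell by 1.02 (adjusted p = 0.0298 and 0.0353). FBN1, a matrix gene, fell by 1.63 (adjusted p = 0.0144).

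edgeR called 76 genes in the mean of both clones, 26 higher and 50 lower, of which DESeq2 also called 75 among its 557. A change in KO1 alone can give such a call. CHCHD2, TTN, PKIB and ZNF229 were called lower (edgeR adjusted p = 0.00547, 0.00398, 0.0106 and 0.0106). Their log2 fold changes in KO2 were 1.20, -0.48, 0.02 and -0.16, none past the threshold. The count was 189 and 55 without WT replicate 1 and 2, 7 and 10 without KO1 replicate 1 and 2, and 8 and 4 without KO2 replicate 1 and 2, with the sign of all 76 kept. In that order, 56, 34, 6, 9, 6 and 3 of the 76 genes were still called. OTX1 kept its call in all of these fits, and PAX6 lost its call only without KO2 replicate 2 (adjusted p = 0.0508).

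**Figure D1:**
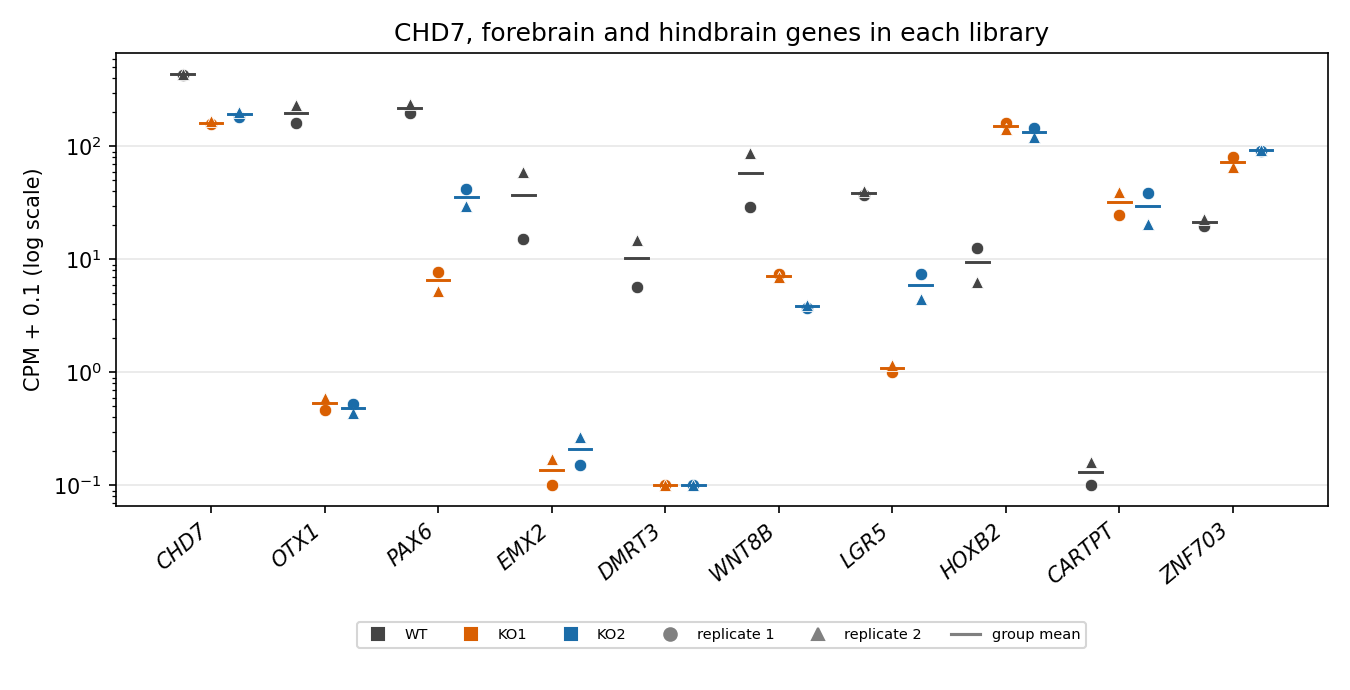
Levels of CHD7 and of 9 genes named in the text, in CPM plus 0.1 on a log axis, with 1 point per library (circle, replicate 1; triangle, replicate 2) and a bar at the mean of each group. OTX1 lay near 196.2 CPM in WT and below 1 CPM in all 4 clone libraries, whereas HOXB2 lay near 9.3 CPM in WT and above 100 CPM in the clones.

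The fixed lists showed the same regional pattern. Of 21 tested genes of telencephalon and forebrain patterning, 20 were lower in KO1 and 19 in KO2, with median log2 fold changes of -2.71 and -2.96 (camera adjusted p = 2.17e-14 and 2.26e-15). With an estimated correlation the adjusted p was 0.512 and 0.33. OTX1 and TCF7L2 were called lower in KO1 and OTX1 in KO2. Adjusted over the list alone, 15 genes were lower in each clone and 1 was higher in KO1. FEZF2, a factor of deep layer cortical neurons, had 24 and 492 counts in the WT libraries, 0 and 0 in KO1, and 2 and 2 in KO2. LHX2, in contrast, had 205 and 45 counts in WT and 327 and 355 in KO1, and did not pass over all genes (adjusted p = 0.412).

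HOX genes were higher as a list. Of 12 tested, 11 were higher in KO1 and 10 in KO2, with medians of 3.36 and 3.55 (camera adjusted p = 1.29e-09 and 1.08e-10, and 0.215 and 0.174 with an estimated correlation). With members at 0 counts placed at the floor, the KO2 median was 3.68 and the KO1 median was unchanged. HOXB2 alone was called over all genes, and 8 genes in KO1 and 9 in KO2 were higher adjusted over the list alone. HOXB3 had 10.8 ± 8.29 CPM in WT, 195 ± 66.7 in KO1 and 156.8 ± 21.2 in KO2 (edgeR adjusted p = 0.0696 and 0.0798). The wider list of midbrain, hindbrain and spinal cord genes had medians of 0.64 and 1.10, with 17 and 15 of 25 genes higher (camera adjusted p = 0.00764 and 0.000267, and 0.723 and 0.376 with an estimated correlation). HOXB2 was its called member in each clone. In each clone 8 genes were higher adjusted over the list alone, while 2 were lower in KO1 and 1 in KO2. The KO1 call of this list was lost without KO1 replicate 1 (adjusted p = 0.128).

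Genes of postmitotic neurons were higher as a list and progenitor genes slightly lower, but the WT and KO2 libraries overlapped on both lists. In replicates 1 and 2, the neuron list had a mean log2 CPM of 6.4 and 4.9 in WT, 6.82 and 6.87 in KO1, and 6.21 and 6.82 in KO2. The list of neuroepithelium and radial glia had 6.92 and 7.47 in WT, 6.65 and 6.49 in KO1, and 6.94 and 6.89 in KO2. Of 31 genes of postmitotic neurons, 30 were higher in KO1 and 29 in KO2, with medians of 1.30 and 0.80 (camera adjusted p = 3.65e-08 and 1.77e-05, and 0.725 and 0.597 with an estimated correlation). None was called over all genes, and 2 in KO1 and 0 in KO2 were higher adjusted over the list alone. CNTN2, an axonal adhesion gene, had 29.8 ± 19.7 CPM in WT, 257.2 ± 14.2 in KO1 and 186 ± 111.6 in KO2 (edgeR adjusted p = 0.133 and 0.205). The WT libraries differed on this list by more than the KO2 libraries did. The KO2 call was lost without WT replicate 2 and without KO2 replicate 2, where the mean log2 fold change of 0.86 became 0.11 and 0.52. For the mean of both clones the value of 1.03 became 0.27 without WT replicate 2. The size of the rise in KO1 also depended on WT replicate 2, since the KO1 libraries lay much closer to WT replicate 1. Neuroepithelium and radial glia genes were slightly lower, with 21 and 19 of 28 lower and medians of -0.37 and -0.12 (camera adjusted p = 0.0126 and 0.0489, and 0.723 and 0.597 with an estimated correlation). PAX6 was called in each clone, and 6 genes in KO1 and 4 in KO2 were lower adjusted over the list alone. This call was lost without WT replicate 2 (adjusted p = 0.682 in KO1 and 0.848 in KO2), in KO1 also without KO1 replicate 2 (0.0605), and in KO2 also without KO2 replicate 1 (0.0646) or 2 (0.139). The lists of neurogenesis regulators, with medians of 0.06 and 0.11, and of proliferation, with -0.12 and 0.03, did not pass in either clone (camera adjusted p = 0.504 and 0.588, and 0.475 and 0.682), and no member was called, with 1 neurogenesis regulator lower in KO2 adjusted over the list alone.

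Endothelium and blood genes were higher in both clones. Of 15 tested, 12 were higher in each, with medians of 1.86 and 2.15 (camera adjusted p = 4.93e-05 and 9.49e-07, and 0.256 and 0.174 with an estimated correlation). No member was called over all genes, and 8 in each clone were higher and 1 in KO1 was lower adjusted over the list alone. GATA2, a factor of blood progenitors that also marks some brainstem neurons, had 1.81 ± 0.559 CPM in WT, 8.94 ± 0.843 in KO1 and 9.65 ± 1.7 in KO2 (edgeR adjusted p = 0.0847 and 0.0798). The endothelial genes VWF and CLDN5 had log2 fold changes of 2.53 and 1.45 in KO1 and 2.38 and 1.51 in KO2, none past the threshold. Levels were low, with a mean log2 CPM of the list between 0.36, in WT replicate 2, and 2.17, in KO2 replicate 1. The list members PECAM1, ERG, GATA1, PTPRC and HBZ had too few counts to be tested, at most 12 in any library. The values therefore do not show whether endothelial or blood cells were present. Hypoxia and glycolysis genes had a median of -0.18 in KO1 and 0.26 in KO2 (camera adjusted p = 0.0186 and 0.0489, and 0.723 and 0.597 with an estimated correlation), with no member called and none past the threshold adjusted over the list alone. The KO1 call was lost without WT replicate 2 (0.0628) or KO1 replicate 1 (0.123). The KO2 call was lost without WT replicate 1 (0.203), WT replicate 2 (0.1) or KO2 replicate 1 (0.588), and with RLE size factors (0.0501).

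In KO2, 6 more lists passed. Dorsal midline genes, of roof plate, cortical hem and choroid plexus, were lower in 18 of 20 (median -1.08, camera adjusted p = 1.08e-10, and 0.266 with an estimated correlation). WNT2B was called, and 11 genes were lower adjusted over the list alone. The 5 others were higher: pluripotency (median 2.89, camera adjusted p = 1.08e-10, and 0.466 with an estimated correlation), surface ectoderm and epithelium (2.33, 1.07e-10, and 0.33), endoderm (3.53, 9.49e-07, and 0.33), mesoderm and heart (0.63, 0.00684, and 0.33) and genes of 20q11.21 (0.35, 0.0118, and 0.33). No member of these 5 was called over all genes. Adjusted over the list alone, 15 of 20 pluripotency genes, 11 of 18 surface ectoderm genes, 8 of 15 endoderm genes and 7 of 15 mesoderm genes were higher, 1 endoderm and 1 mesoderm gene were lower, and 0 of 19 genes of 20q11.21 passed. The 20q11.21 call was lost without KO2 replicate 2 (adjusted p = 0.22).

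**Figure D2:**
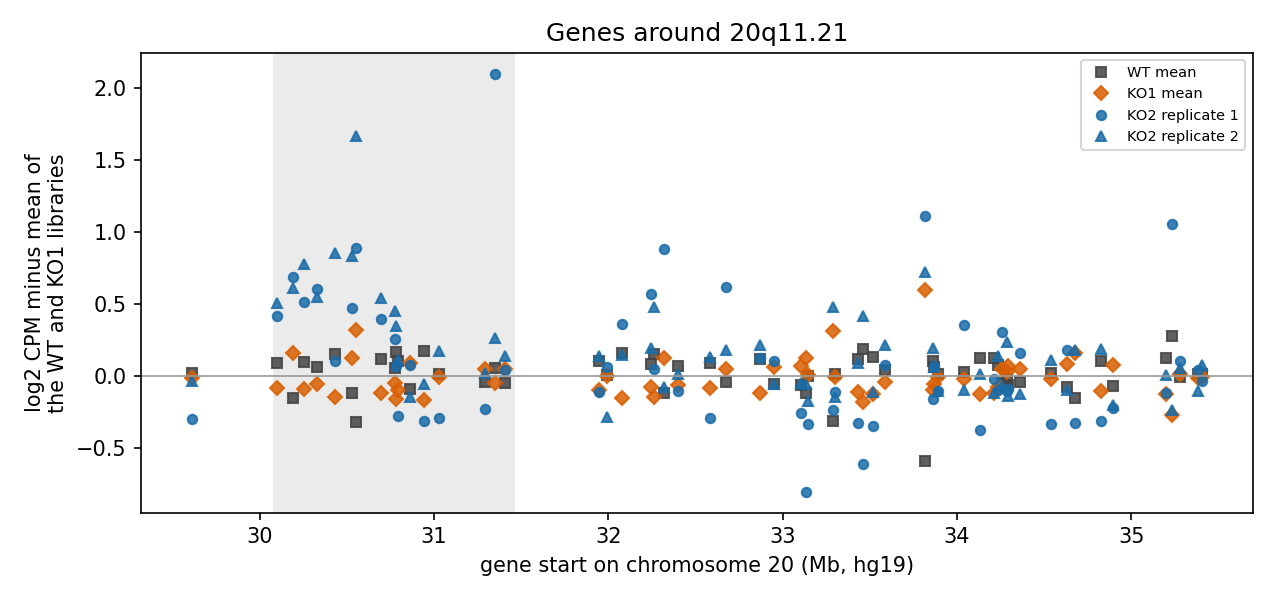
Log2 CPM minus the mean of the WT and KO1 libraries, against gene start on chromosome 20 in Mb (hg19), for the WT mean, the KO1 mean and each KO2 library, with 20q11.21 shaded. In the shaded region the median was 0.25 in KO2 replicate 1 and 0.45 in KO2 replicate 2.

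Pluripotency transcripts were above WT in both KO2 libraries and highest in replicate 1. The 9 list members under 1 CPM in WT had a median log2 difference from WT of 7.69 in KO2 replicate 1 and 4.12 in KO2 replicate 2, and the list still passed without replicate 1 (camera adjusted p = 7.73e-12). In the complete data its adjusted p was 0.466 with an estimated correlation and 0.216 with fry. NANOG, a core stem cell factor, had 763 counts there, 44 in KO2 replicate 2 and 0 in each WT and KO1 library. POU5F1 had 571 and 43 counts in the KO2 libraries and at most 1 elsewhere, and TDGF1 had 3758 and 190. Some markers in the other lists moved with them: the epithelial cadherin gene CDH1 had 3284 and 299 counts in the KO2 libraries, the mesodermal and endothelial receptor gene KDR 1362 and 106, and the endodermal gene CER1 1302 and 42. Other members did not follow replicate 1: HAND1 had 117 and 140 counts, CDX2 39 and 37, and GATA2 205 and 149. Without KO2 replicate 1, 13 lists still passed in KO2, of which 11 were among the 13 of the complete data.

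Camera called 7 lists in KO1, 13 in KO2 and 10 in the mean of both clones, and with an estimated correlation no list passed in any comparison. fry passed 3 lists in KO1 and in the mean of both clones, namely telencephalon and forebrain patterning, HOX genes and endothelium and blood, and 4 in KO2, where roof plate genes joined them. The other lists did not pass against WT in either clone. In the order KO1 and KO2, the camera adjusted p was 0.645 and 0.402 for eye field and retina (medians 0.31 and 0.49), 0.645 and 0.096 for ventral forebrain (medians 0 and 1.43), 0.853 and 0.963 for neural crest, 0.645 and 0.0924 for placode and otic, 0.913 and 0.167 for mesenchyme and extracellular matrix, 0.865 and 0.588 for p53 targets, and 0.587 and 0.0924 for the unfolded protein and integrated stress response. It was 0.839 and 0.493 for the Notch pathway, 0.865 and 0.482 for WNT targets, 0.191 and 0.215 for BMP and TGF-beta targets, 0.797 and 0.588 for hedgehog targets, 0.504 and 0.431 for CHD remodelers, 0.413 and 0.588 for Polycomb and Trithorax genes, 0.328 and 0.588 for axon guidance and cell adhesion, and 0.328 and 0.588 for imprinted genes. LGR5 among the WNT targets and CHD7 among the CHD remodelers were called in KO1 despite this.

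**Figure D3:**
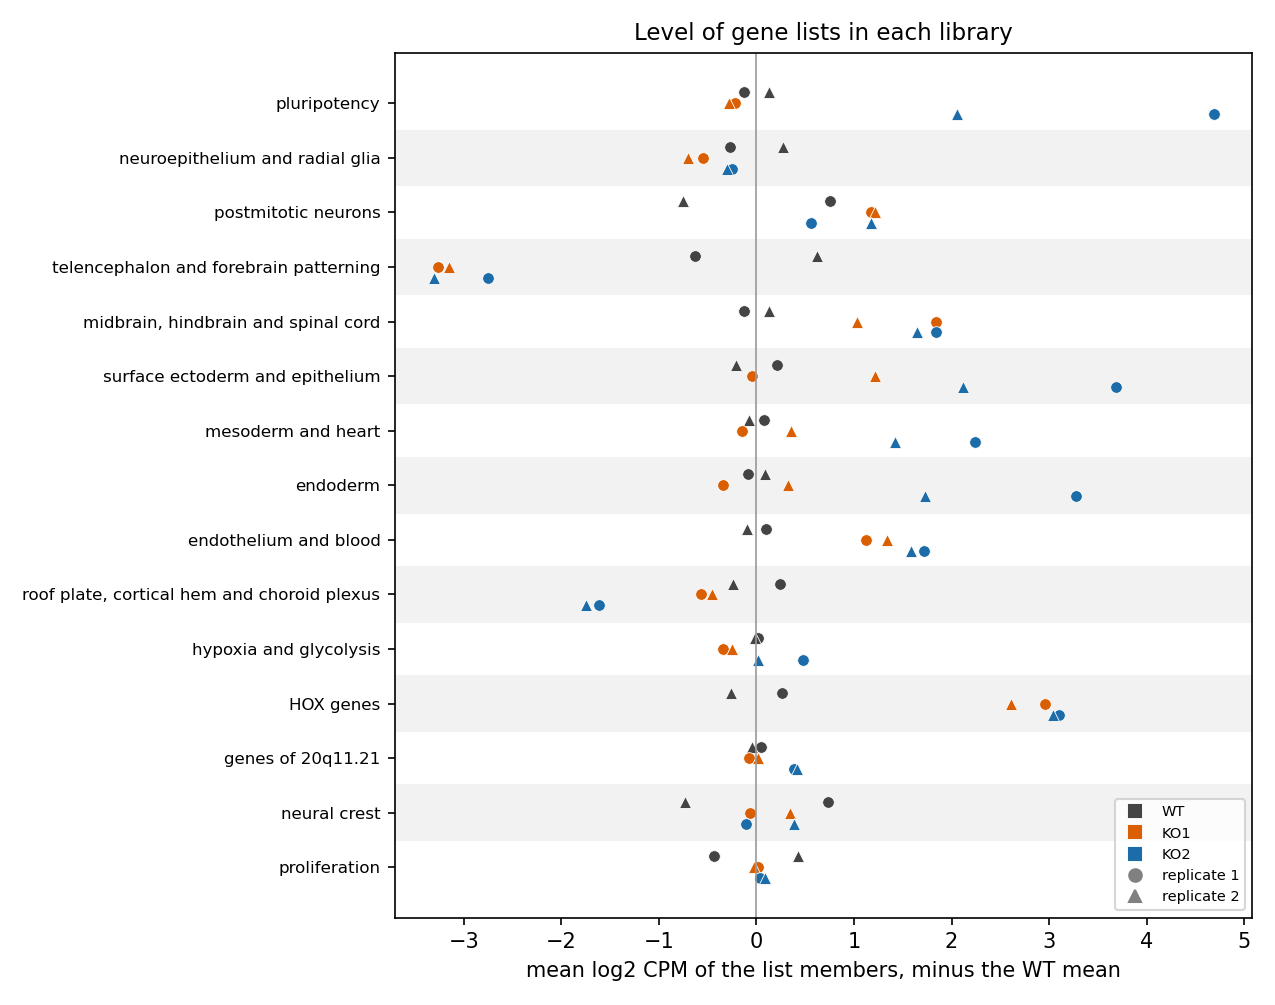
Mean log2 CPM of the tested members of 15 lists in each library, minus the mean of the WT libraries (circle, replicate 1; triangle, replicate 2). The forebrain list lay below both WT libraries in all 4 clone libraries and the HOX list above them, and the pluripotency list had a mean log2 CPM of 6.56 in KO2 replicate 1 and 3.93 in KO2 replicate 2 against 1.75 and 2 in WT.

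The contrast of KO2 with KO1 tested the difference between the clones itself. CHCHD2, at 0 counts in KO1, had 217.5 ± 5.43 CPM in KO2, at least 2180-fold higher (edgeR adjusted p = 0.00235). ZNF737 and ZNF229 were at least 191-fold and at least 134-fold higher in KO2 (adjusted p = 0.0162 for both), and ZNF253, with 4 counts in KO1, was higher by 6.63 on the log2 scale (adjusted p = 0.0332). TTN and PKIB were higher in KO2 by 4.68 and 4.36 (adjusted p = 0.0028 and 0.00747), and ZDHHC4 by 2.49 (adjusted p = 0.0391). ZNF141 had 1 count in KO2, a ratio of 909 (95% counting interval 163 to 35900, adjusted p = 0.0332). ATOH1, a proneural factor of the hindbrain and inner ear, had a log2 difference of -2.51, with 60.5 ± 14.3 CPM in KO1, 10.6 ± 0.432 in KO2 and 35.5 ± 0.758 in WT (adjusted p = 0.0332). TPBG and BTBD11 had differences of -1.78 and -1.73 (adjusted p = 0.0391 for both).

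These were all 11 genes called, 7 higher and 4 lower in KO2, and 1244 genes had an unadjusted p under 0.05. DESeq2 called 318, with all 11 among them. Differences in PAX6 (2.46, edgeR adjusted p = 0.0797), WNT2B (-2.55, 0.0536) and WNT4 (-1.91, 0.0507) did not pass. The count was 36 and 39 without WT replicate 1 and 2, 1 without either KO1 library, 0 without KO2 replicate 1 (871 at an unadjusted p under 0.05) and 32 without KO2 replicate 2. In that order, 11, 11, 1, 1, 0 and 5 of the 11 genes were still called. Camera passed 12 lists between the clones, 10 higher and 2 lower in KO2, and none with fry or with an estimated correlation, where the smallest adjusted p was 0.311. Roof plate genes had a median of -1.08 (camera adjusted p = 4.44e-11), with 11 lower adjusted over the list alone, whereas the forebrain and HOX lists did not pass (adjusted p = 0.673 for both).

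**Figure D4:**
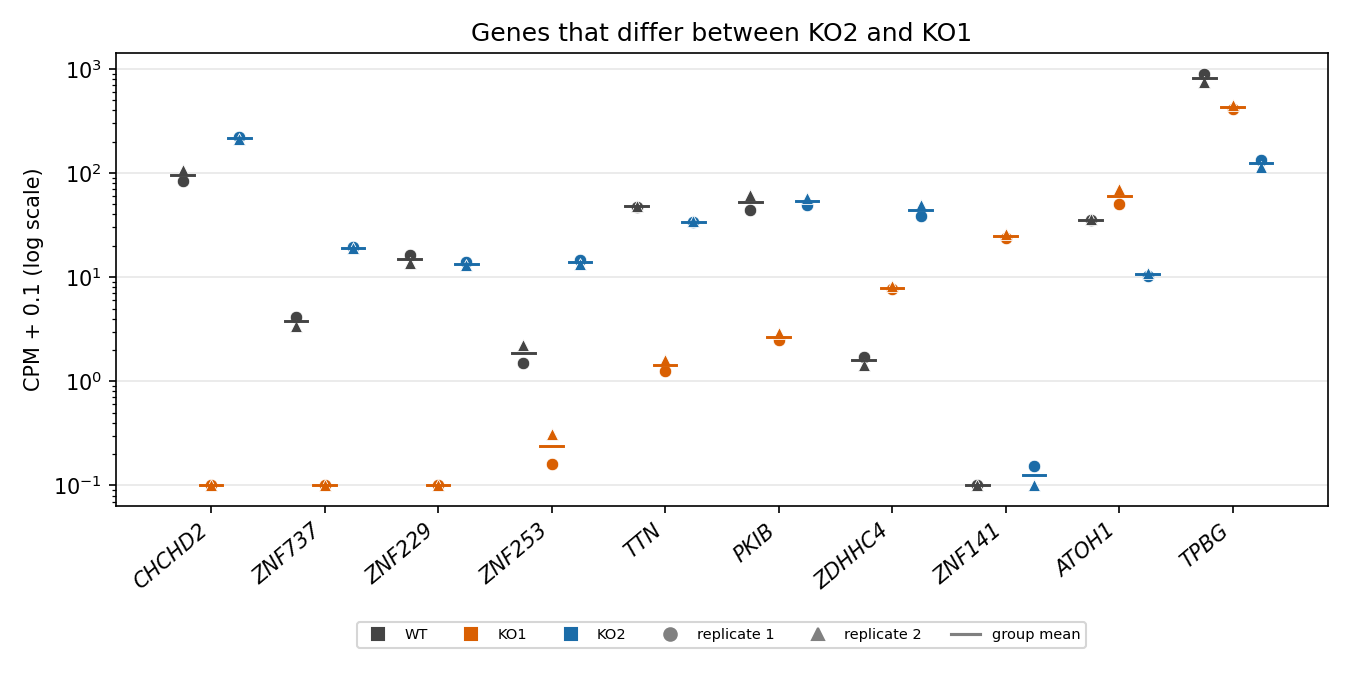
Levels of 10 of the genes called between KO2 and KO1, in CPM plus 0.1 on a log axis, with 1 point per library (circle, replicate 1; triangle, replicate 2) and a bar at the group mean. CHCHD2, ZNF737 and ZNF229 had 0 counts in both KO1 libraries, and ZNF141 had 0 counts in both WT libraries.

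The authors' deposited table for KO1 held 430 genes, all lower, with log2 fold changes from -12.81 to -0.59 and a median of -1.51. Of these, 395 were matched by symbol to a tested gene and all 395 had the same sign in the edgeR fit, which called 15 of them. The authors' deposited table for KO2 held 341 genes, all higher, with a median of 2.96, of which 298 were matched, all with the same sign, and 5 were called by edgeR. The deposited tables were made from these libraries, so their direction is not independent evidence. No chromosome moved as a whole in either clone: camera over chromosomes gave a smallest adjusted p of 0.12, for chromosome 19 in KO1 with a median of -0.11.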

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

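Among the tests in this part, that of CHD7 loss itself and both tests of 20q11.21 were chosen after the result was seen, and the test of other stem cell genes was fixed before their values were looked at.

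All results here differ between the clones by a test of the difference itself, KO2 minus KO1. On the log2 scale the genes were CHCHD2 at 14.83, ZNF737 at 11.32, ZNF229 at 10.81, ZNF253 at 6.63, TTN at 4.68, PKIB at 4.36, ZDHHC4 at 2.49, BTBD11 at -1.73, TPBG at -1.78, ATOH1 at -2.51 and ZNF141 at -9.47. The fitted values of CHCHD2, ZNF737, ZNF229 and ZNF141 depend on the prior count, because 1 clone had 0 or 1 counts, and the bounds in the report replace them. The nearest tested genes on either side of each of these had median differences between -0.33 and 0.81, with a smallest edgeR adjusted p of 0.177. With only 11 of 16285 genes called, this cannot tell whether a wider stretch was affected. ZNF253 and ZNF737 both lie on chromosome 19 (starts at 19976639 and 20720798, hg19). Each was lower in KO1 and higher in KO2 than in WT, though not all of these changes passed the threshold. Lists that differed had medians of 2.92 for pluripotency, 2.25 for surface ectoderm and epithelium, 3.29 for endoderm, 1.37 for mesoderm and heart, 1.37 for ventral forebrain, 0.52 for placode and otic, 0.57 for mesenchyme and extracellular matrix, 0.5 for hypoxia and glycolysis, 0.3 for the unfolded protein and integrated stress response, 0.49 for genes of 20q11.21, -0.36 for postmitotic neurons and -1.08 for roof plate genes. With an estimated correlation their adjusted p lay between 0.311 and 0.783. The postmitotic neuron call was lost without KO1 replicate 1 (adjusted p = 0.0866), KO1 replicate 2 (0.1) or KO2 replicate 1 (0.999). The mesenchyme call was lost without any 1 library other than KO1 replicate 2 (adjusted p 0.128 to 0.955), the placode call without KO2 replicate 1 (0.0798) or 2 (0.515) and with the stricter filter (0.826, mean 0.04 against 0.91), the unfolded protein call without KO2 replicate 1 (0.444), and the 20q11.21 call without KO2 replicate 2 (0.0789).

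Stem cell transcripts were above WT in both KO2 libraries, by a median log2 of 7.69 and 4.12, and most in KO2 replicate 1, where the 9 pluripotency genes under 1 CPM in WT had a median 14.3-fold (quartiles 8.48 and 18.3) above KO2 replicate 2. Loss of CHD7 by itself is argued against as a common cause, since these genes stayed at 5 counts or fewer in every WT and KO1 library. Their median of 0.902-fold of WT in the KO1 libraries depends on the prior count and is not a measured fold. Cells that remained in the stem cell state are a candidate explanation: 8 stem cell genes outside the fixed lists and under 1 CPM in WT had a median 16.8-fold difference between the KO2 libraries (quartiles 13.9 and 22.4), and all 13 that could be tested, at any level in WT, a median of 13.6-fold. The limit to genes under 1 CPM in WT was not part of the test as first written. A difference between the clones in leaving the stem cell state could give similar ratios, so the test does not separate these explanations. That difference stays open and was not tested.

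Genes of 20q11.21 (chromosome 20, 30102213 to 31438211, hg19), a region often gained in cultured human stem cells, were set against the mean of the WT and KO1 libraries. They were shifted by a median of 0.25 and 0.45 in the KO2 libraries. The WT and KO1 libraries lay between -0.03 and 0.06, but they are centred by this choice of reference. Of 17 genes, 8 had both KO2 libraries above the 4 others, as did 5.6 percent of 12084 tested genes with a mean of at least 5 CPM. Among the 8 was DNMT3B, also a member of the pluripotency list, with a shift of 2.1 in KO2 replicate 1 and 0.26 in KO2 replicate 2. Stem cells in KO2 replicate 1 were tested as a cause by comparing the shifts of the KO2 libraries. The shift did not follow the stem cell transcripts: it was smaller in replicate 1, with a difference of -0.20 and 4 of 17 genes larger there. The bound for this test was rewritten after its value was seen, because as first written, a difference within 0.15 either way, it left the value undecided. No conclusion on this cause is therefore drawn. An extra copy of the region may contribute but was not settled: the shift exceeded 97.4 percent of 11716 equal runs of neighbouring genes in 1 KO2 library and 99.9 percent in the other, where 99 percent in both had been asked for, and 3 copies over 2 would give a log2 shift of 0.58. The shift was uneven within the region, with medians of 0.47 and 0.61 from HM13 to TSPY26P and of -0.09 and 0.12 from PLAGL2 to MAPRE1, but these parts were chosen after their values were seen and decide nothing.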

How the results depend on the processing

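The alternatives for lists between the clones and for chromosomes were chosen after the result was seen. In the order KO1, KO2, mean of both clones, KO2 against KO1, and both clones the same way, the counts of called genes were 24, 17, 76, 11 and 12. RLE size factors kept all counts within 1.5 times. Without a low-count filter they were 176, 126, 227, 26 and 76, and with the stricter filter KO2 had 40. DESeq2 gave 530, 521, 557, 318 and 240, and limma-voom gave 42 for the mean, 6 between the clones and 7 in both. In fits of only the 2 groups compared, with fewer samples, they were 8 for KO1, 9 for KO2, 38 between the clones and 2 in both. CHD7 in KO2 passed at -1.174 without a filter, -1.171 with the stricter filter and -1.171 with DESeq2, and CHD7 in KO1 no longer passed at -1.426 in the fit of 2 groups (adjusted p = 0.0796). The cause of these moves was not tested.

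The replicate numbers of the labels are shared by the groups. The deviations of same-numbered libraries had correlations of -0.08, -0.16 and -0.12 across genes, so no shared deviation was seen. A common batch is not excluded, because differences particular to each group could hide it. With the replicate number as a block the counts were 8 for KO1, 23 for the mean, 3 between the clones and 4 in both. CHD7 no longer passed, at -1.421 in KO1 (edgeR adjusted p = 0.107) and -1.299 in the mean of both clones (0.0566). The KO2 calls of the hypoxia and neuroepithelium lists were lost with the block (adjusted p = 0.053 for both), and that of the hypoxia list with RLE size factors (0.0501). Of 63 results for named genes, 23 kept their call with the block and 40 lost it. In fits of only the 2 groups compared, 19 kept it and 19 lost it. The block leaves fewer residual degrees of freedom.

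Leaving out each library in turn gave 2 to 212 genes in KO1, 3 to 65 in KO2, 4 to 189 in the mean, 0 to 39 between the clones and 1 to 47 in both. CHD7 lay between -1.461 and -1.381 in KO1 and between -1.252 and -1.092 in KO2. Lists past the threshold numbered 6 to 10 in KO1, 11 to 17 in KO2, 10 to 15 in the mean and 8 to 13 between the clones. With an estimated correlation 0 lists passed in any of the 4 comparisons, and with fry 3, 4, 3 and 0. The list of postmitotic neurons between the clones turned from a mean of -0.33 to -0.01 without KO2 replicate 1 (camera adjusted p = 0.999), the only result whose tested direction reversed, and to -0.56 without KO2 replicate 2. The mean of the mesenchyme list between the clones was 0.46 and became -0.06 without KO1 replicate 1, with its tested direction unchanged (camera adjusted p = 0.955). Under the stricter filter some lists had too few genes and were not run, and the placode list between the clones fell to a mean of 0.04 (adjusted p = 0.826). Of 63 results for named genes, 63 kept their call with RLE size factors and with no filter, 62 with DESeq2, 34 with limma-voom and between 10 and 55 when 1 library was left out, always in the same direction. Chromosome shifts stayed at 0 past the threshold in every setting run, and the 20 matched genes of the deposited tables called here were also called with a fold of at least 2.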

Other observations

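Among the tests in this part, those of the WT difference and of neural progenitors were chosen after the result was seen, and the test of retinoid targets was fixed before their values were looked at.

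Some members of lists that did not pass against WT had these values, none of them past the threshold. RTL1, an imprinted gene, had 0.274 ± 0.306 CPM in WT, 3.2 ± 1.42 in KO1 and 2.75 ± 0.603 in KO2, and the imprinted gene DLK1 32.6 ± 18.2, 71.1 ± 16.5 and 99.5 ± 12.7 CPM (SD, n = 2 each). The edgeR adjusted p for the mean of both clones was 0.161 and 0.232. MYC had 11.4 ± 1.55, 25.1 ± 8.41 and 41.7 ± 3.95 CPM (adjusted p = 0.0759), and COL6A3, a collagen gene, 0.237 ± 0.0747, 5.38 ± 5.61 and 28.6 ± 6.09 CPM (adjusted p = 0.0848).

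In both clones the list of telencephalon and forebrain patterning was lower and HOX genes higher, while the ventral forebrain list (medians 0 and 1.43) and the eye field list (0.31 and 0.49) did not pass in either direction. The WT and clone libraries did not overlap on either list. The patterning list had a gap of 2.12 on the mean log2 CPM from the lowest WT to the highest clone library, against 1.26 between the WT libraries. The HOX list had a gap of 2.34. These lists were taken up because they already differed between WT and clones. With 2 WT libraries, 1 difference does not bound how far other WT cultures could lie, so variation among WT cultures is not excluded as a cause. Neural progenitor genes in general fell less than the patterning list: the neuroepithelium list had a median of -0.37 in KO1 and -0.12 in KO2, against -2.71 and -2.96. This does not tell whether progenitors of the forebrain in particular were fewer, because the list covers neural progenitors of all regions. Its member PAX6 had -5.08 and -2.62. The limits of this test were also set after the values were seen, so it decides nothing on fewer progenitors. A stronger retinoid response in the clones is a candidate explanation, as a hypothesis. The 20 retinoid targets outside the HOX genes had medians of 0.58 in KO1 and 0.77 in KO2, with 15 and 17 higher. However, only TSHZ3 was called in the mean of both clones. CYP26A1, a direct target, had -3.46 and -2.18 in KO1 and KO2, while CYP26C1 had -5.84 and 0.69 and CYP26B1 5.01 and 5.54. Targets such as MEIS2 also mark the hindbrain, so the test does not separate signal from regional identity. An effect of isolating clones stays open, since the labels name no unedited clone, and so does loss of CHD7 itself.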
